A study of Mus musculus with 12 samples.

How the data were processed

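The data were 1 table of 28004 genes in 12 libraries of Acta2-dsRed and Pdgfra-GFP double-positive mouse lung cells, at E17.5, P3, P7 and P10, with 3 libraries per stage. Per the labels, whole lung was dissociated and cells were sorted by both reporters. RNA was made into stranded libraries with a low-input total RNA kit, although the molecule label names polyadenylated RNA. Per the submitters' processing notes the genome build was GRCm38; the aligner, quantifier and gene annotation are not given in the sources used here. The deposited values are estimated counts that the authors scaled and rounded to whole numbers, as read from the values themselves. Genes with transcripts up to 120 nt had low values near 40.9 where genes over 1500 nt had values of 1, as a length scaling would give. A value of a short gene is therefore not a number of reads, and no limit from a count of 0 is given.

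Each library was assigned to its stage from its label. Gene symbols were matched to GENCODE mouse release 21, which gave a position for 26408 genes (94.3%); coordinates are from that annotation, and RP23-372C7.2 and RP23-372C7.5 had none. Estimated counts summed to between 13328600 and 18740600 per library, and this depth limits low genes most. CPM were computed with TMM library sizes. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) after the edgeR filter on low counts by stage, with 1 model over all 12 libraries, robust fitting and Benjamini-Hochberg adjustment at 0.05 over 16827 genes. The median prior degrees of freedom were 2.61 and the common dispersion 0.145. Every adjusted p of a gene is from this test unless another is named. Values are means ± SD of 3 libraries.

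Gene lists, 31 in number, were fixed before the data were examined, as were the comparisons, the named-gene rule and most alternatives. The 29 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over 116 tests of lists and comparisons, and again with an estimated correlation and with fry. Mesothelial markers had 4 tested members and were not tested as a set. The named genes were the reporter genes, Yap1, Wwtr1, Ccn1 (Cyr61 in the table), Ccn2 (Ctgf) and Ankrd1. They were also, per comparison, the 8 highest and 8 lowest fold changes among genes that passed, reached 10 CPM and did not overlap between stages, with up to 4 members of each list and the 6 leading reversals in each direction, without predicted models. The reversal test used comparisons that share no library, though the model gives both the same estimate of the spread per gene.

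Counts were simulated for 16827 genes with 200 genes changed, besides the members of a shifted list. The test recovered 4.48% of 1.5-fold, 29.9% of 2-fold and 59.1% of 4-fold changes for P3 vs E17.5, with 6 of 74 calls false. For P7 vs P3 it recovered 2.99%, 26.9% and 51.5%, with 1 of 60 calls false, for P10 vs P7 1.49%, 16.4% and 57.6%, with 6 of 60 false, and for P10 vs E17.5 2.99%, 20.9% and 65.2%, with 3 of 69 false. Fewer genes changed in the simulation than passed in the real P3 vs E17.5 (4225), P10 vs P7 (613) and P10 vs E17.5 (3077). In P7 vs P3 1 gene passed, but 2399 had an unadjusted p under 0.05 where chance gives 841. The shares recovered therefore do not measure the power of any of the 4 comparisons. A simulated shifted list was found for each comparison and 0 unshifted lists passed. Genes were simulated independently of each other, so this could not show false calls of lists whose genes are correlated.

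The alternatives were other scalings, filters, DESeq2 1.42.0, limma-voom, a fit on the 6 libraries compared, a replicate block, a minimum fold of 1.5, each library left out, and 7 settings chosen after seeing the data. Xist lay between 85.1 and 135 CPM in the libraries and Y-linked genes summed to at most 5.80 CPM, so no sex term was used.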

Results

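Bulk RNA sequencing was analysed for 12 libraries of mouse lung cells that carried both an Acta2-dsRed and a Pdgfra-GFP reporter, sorted by flow cytometry from dissociated whole lung. Acta2 encodes smooth muscle actin and Pdgfra a platelet-derived growth factor receptor, and cells with both include the myofibroblasts of the growing alveolar wall. The libraries covered embryonic day E17.5 and postnatal days P3, P7 and P10, with 3 libraries per stage. Estimated counts summed to between 13328600 and 18740600 per library, and between 20234 and 21235 genes were above 0. The 7SL and 7SK small RNA genes took up to 46.3% of the summed estimated counts of a library. These values look length-scaled, so this is not a share of reads. The series title places the study in Hippo pathway activity during alveolar morphogenesis. The comparisons asked what changed in these cells across birth, in the first postnatal week and up to P10. Nothing in the labels says that the libraries of a stage came from separate animals, so p-values measure only the spread between these samples, which may be technical. Positions are on the mouse build GRCm38.

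Across the 4 stages, 5401 of 16827 tested genes (32.1%) differed. Spearman correlations of libraries lay between 0.938 and 0.961 within a stage and between 0.872 and 0.954 between stages. The reporter genes themselves moved with age. Acta2 (chromosome 19, 34241090 to 34255590, minus strand) stood at 492 ± 182 CPM at E17.5, 1025 ± 46.4 at P3, 822 ± 131 at P7 and 487 ± 166 at P10 (SD, n = 3). It rose from E17.5 to P3 with a log2 fold change of 1.06 (SE 0.28, adjusted p = 0.0183). That call ended without E17.5 replicate 1 (0.86, adjusted p = 0.0543) and without E17.5 replicate 2 (0.98, adjusted p = 0.0724). Pdgfra (chromosome 5, 75152292 to 75198215, plus strand) stood at 346 ± 71.9, 179 ± 24.1, 191 ± 25.5 and 221 ± 38.0 CPM in the same order, with a log2 fold change of -0.95 (SE 0.19, adjusted p = 0.00430) from E17.5 to P3.

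**Figure D1:**
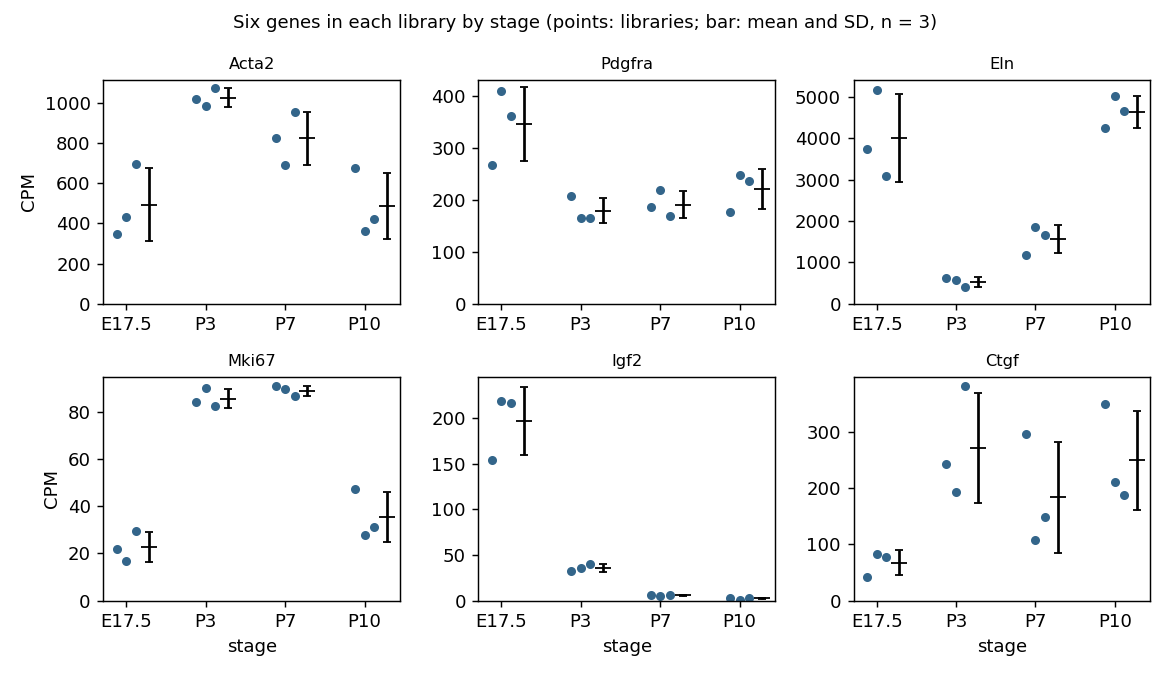
Levels of Acta2, Pdgfra, Eln, Mki67, Igf2 and Ctgf in CPM (vertical axes) in each library at each stage (horizontal axes); points are the 3 libraries, and the bar beside them gives their mean and SD. Mki67 averaged 22.7 CPM at E17.5, 85.6 at P3, 89.1 at P7 and 35.5 at P10, and Eln 4001, 533, 1569 and 4633.

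Across birth, from E17.5 to P3, genes of DNA replication and mitosis rose and fetal growth genes fell. All 22 DNA replication genes rose, with a median log2 fold change of 2.13. Among them, Rrm2, a subunit of ribonucleotide reductase, went from 5.28 ± 1.22 to 45.9 ± 4.76 CPM (log2 fold change 3.11, SE 0.30, adjusted p = 8.33e-05). Mcm3 of the replicative helicase went from 8.29 to 38.9 CPM (2.22, SE 0.19) and Fen1, a flap endonuclease, from 3.78 to 16.1 CPM (2.08, SE 0.16). The list passed with the preset correlation (adjusted p = 7.74e-33) and with an estimated correlation (adjusted p = 0.0492), and 22 members passed adjusted over the list alone. Of 20 mitosis genes 19 rose, 20 adjusted over the list alone, among them Mki67 (22.7 ± 6.49 to 85.6 ± 4.07 CPM), Top2a (19.5 to 76.3) and Aurkb (2.43 to 15.5). The mitosis list passed with the preset correlation (adjusted p = 5.95e-20) and had adjusted p = 0.251 with an estimated correlation.

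Of 16 fetal growth and imprinted genes, 13 fell and 1 rose in P3 vs E17.5, with the same counts adjusted over the list alone (median log2 fold change -1.16, adjusted p = 3.67e-10, and adjusted p = 0.0225 with an estimated correlation). H19, a maternally expressed non-coding RNA (chromosome 7, 142575529 to 142578143, minus strand), went from 4386 ± 1115 to 215 ± 29.7 CPM (log2 fold change -4.35, SE 0.37, adjusted p = 4.21e-05). Peg3 went from 232 to 100.1 CPM, Meg3 from 228 to 70.0, and Cdkn1c, a cyclin-dependent kinase inhibitor, from 104 to 52.7. Of 16 pericyte and vascular smooth muscle markers, 6 fell and none rose, and 8 fell adjusted over the list alone (adjusted p = 1.98e-05, and adjusted p = 0.0289 with an estimated correlation). Cspg4 went from 31.7 ± 6.60 to 5.12 ± 0.35 CPM (-2.63, SE 0.16), Rgs5 from 72.5 to 15.3 and Lamc3 from 45.4 to 3.02.

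Matrix genes moved both ways across birth, and contractile genes that passed mostly rose. Of 19 elastic fibre genes 8 fell and 4 rose, the same counts adjusted over the list alone, and the list itself did not pass (adjusted p = 0.0865). Eln, which encodes tropoelastin (chromosome 5, 134702593 to 134747323, minus strand), went from 4001 ± 1068 to 533 ± 124 CPM (log2 fold change -2.91, SE 0.25, adjusted p = 4.83e-05). Lox, a crosslinking enzyme, went from 352 to 32.8 CPM (-3.43, SE 0.20), while Loxl2 went from 108 to 425 CPM (1.97, SE 0.25). Of 17 basement membrane genes 7 fell and 3 rose, 8 and 3 adjusted over the list alone (adjusted p = 0.0149, and adjusted p = 0.340 with an estimated correlation). Lama4 stood at 243 and 93.6 CPM and Lamc1 at 771 and 345 CPM. Of 20 contractile and smooth muscle genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone (adjusted p = 0.0110, and adjusted p = 0.605 with an estimated correlation). Cald1 went from 837 to 1891 CPM and Des from 42.6 to 106 CPM, while Mylk, the myosin light chain kinase, went from 341 to 216 CPM. Without E17.5 replicate 1 the contractile list had adjusted p = 0.0595.

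Of 18 secondary crest myofibroblast markers 7 rose and 7 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.714). Aspn, which encodes the matrix protein asporin, went from 8.71 to 205 CPM (log2 fold change 4.55, SE 0.37), and Hhip, a Hedgehog-binding protein, from 609 ± 135 to 102 ± 11.8 (-2.57, SE 0.17). Of 18 hypoxia and glycolysis genes 8 fell and none rose, also adjusted over the list alone (adjusted p = 0.000377, and adjusted p = 0.258 with an estimated correlation). Bnip3 stood at 168 and 30.7 CPM and Slc2a1, a glucose transporter, at 22.1 and 3.85 CPM. Of 15 adventitial fibroblast markers 3 rose and 2 fell, 4 and 2 adjusted over the list alone (adjusted p = 0.0226, and adjusted p = 0.585 with an estimated correlation). Without E17.5 replicate 3 the adventitial list had adjusted p = 0.0683. Its member Cd34 went from 24.2 to 263 CPM. The summed level of airway epithelial markers moved beside these groups, from 21.4 ± 7.23 to 118 ± 26.8 CPM, and most of this came from Tppp3 (12.6 to 78.9 CPM) and Scgb1a1 (1.74 ± 1.22 to 29.7 ± 21.7 CPM). These were the 2 of 6 tested members that rose, also adjusted over the list alone (list adjusted p = 0.0413, and adjusted p = 0.585 with an estimated correlation). The airway list had adjusted p = 0.107, 0.0744 and 0.145 without E17.5 replicates 1 and 2 and P3 replicate 3. The call of Scgb1a1 ended without E17.5 replicates 2 and 3 and P3 replicate 3 (adjusted p = 0.0712, 0.0642 and 0.0570). The erythroid sum went from 167 ± 34.6 to 57.9 ± 11.9 CPM, and 4 of 6 erythroid markers fell, also adjusted over the list alone (adjusted p = 0.0331, and adjusted p = 0.507 with an estimated correlation). That list had adjusted p = 0.0744 and 0.0750 without E17.5 replicate 2 and P3 replicate 1. The immune sum went from 13.1 ± 1.39 to 27.6 ± 1.70 CPM and the mesothelial sum from 17.6 ± 3.79 to 4.37 ± 0.90. Of 12 immune markers 4 rose, also adjusted over the list alone (adjusted p = 0.0392, and adjusted p = 0.512 with an estimated correlation). The immune list had adjusted p = 0.127 and 0.0582 without E17.5 replicate 3 and P3 replicate 1.

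In the Hippo pathway, the transcripts of the transcriptional coactivators were level. Yap1 stood at 58.8 ± 2.34 and 55.7 ± 5.76 CPM at E17.5 and P3 (log2 fold change -0.08, SE 0.10, adjusted p = 0.639). Wwtr1, which encodes TAZ, stood at 54.0 ± 9.83 and 59.4 ± 12.5 CPM (0.14, SE 0.20, adjusted p = 0.666). Among their targets, Ctgf (Ccn2; chromosome 10, 24595442 to 24598683, plus strand) rose from 67.2 ± 22.3 to 272 ± 97.8 CPM (2.02, SE 0.44, adjusted p = 0.00862). Cyr61 (Ccn1) had 630 ± 134 and 513 ± 24.6 CPM (-0.30, SE 0.35, adjusted p = 0.580). Ankrd1 was too low to test, with between 0 and 28 estimated counts per library. Of 21 tested YAP and TAZ target genes 5 rose and 1 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.233). Tgfb2 went from 16.2 to 79.8 CPM, Myof from 1.75 to 9.93 and F3, tissue factor, had a log2 fold change of -1.76 (SE 0.29). Of 29 Hippo pathway components 6 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.872, median -0.065 and mean 0.0020, of opposite sign). Amotl1 went from 32.6 to 54.5 CPM and Frmd6 from 12.5 to 23.8, while the atypical cadherin Fat4 went from 33.5 to 18.0 and Limd1 from 35.8 to 16.3.

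The genes with the highest fold changes in P3 vs E17.5 included Lrrc15 (log2 fold change 6.67, SE 0.51) and Ntn1, which encodes the guidance protein netrin (1.28 to 43.7 CPM, 5.12, SE 0.31). They also included Prss35 (5.55 to 145) and Enpp1 (1.21 to 30.5). Prokr2, a prokineticin receptor, stood at 0.055 ± 0.050 and 74.7 ± 44.4 CPM, and limma-voom gave it adjusted p = 0.258. Among those with the lowest were Hif3a (53.9 to 1.20 CPM, -5.50, SE 0.33), Zbtb16 (58.4 to 1.85, -4.99, SE 0.38), Scara5 (264 to 6.04) and Cyp1b1 (28.8 to 0.56). Srp54a was listed at 0 in the E17.5 libraries and at 10.5 ± 2.11 CPM at P3, and the pseudogene Rps3a3 at 42.1 ± 67.3 and 0.43 ± 0.22 CPM. Both share sequence with near-identical genes, so their values are uncertain. Rps3a3 had 119.7, 5.26 and 1.20 CPM in E17.5 replicates 1, 2 and 3, so its mean rests on 1 library, and its log2 fold change of -6.60 became -2.81 without it. It had adjusted p = 0.0553, 0.0665 and 0.0601 without P3 replicates 1, 2 and 3. Nor did it stay low, with 65.0, 80.1 and 84.4 CPM in P7 replicates 1, 2 and 3. In P10 replicates 1, 2 and 3 it had 77.9, 56.4 and 65.8 CPM. In all, 4225 genes passed in P3 vs E17.5, 2201 higher and 2024 lower at P3, of which 995 and 848 differed at least 2-fold. Over all tested genes, the 3 libraries of one stage did not overlap the 3 of the other for 38.9%, where chance alone gives 10%. With the preset correlation 13 of 29 lists passed, of which 3 held with an estimated correlation, and other splits of the same 6 libraries gave up to 11 lists. Here and in the other comparisons, such splits hold both stages in each group in unequal numbers. They keep part of the stage difference, so their counts are no chance level and cannot decide on the list calls.

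**Figure D2:**
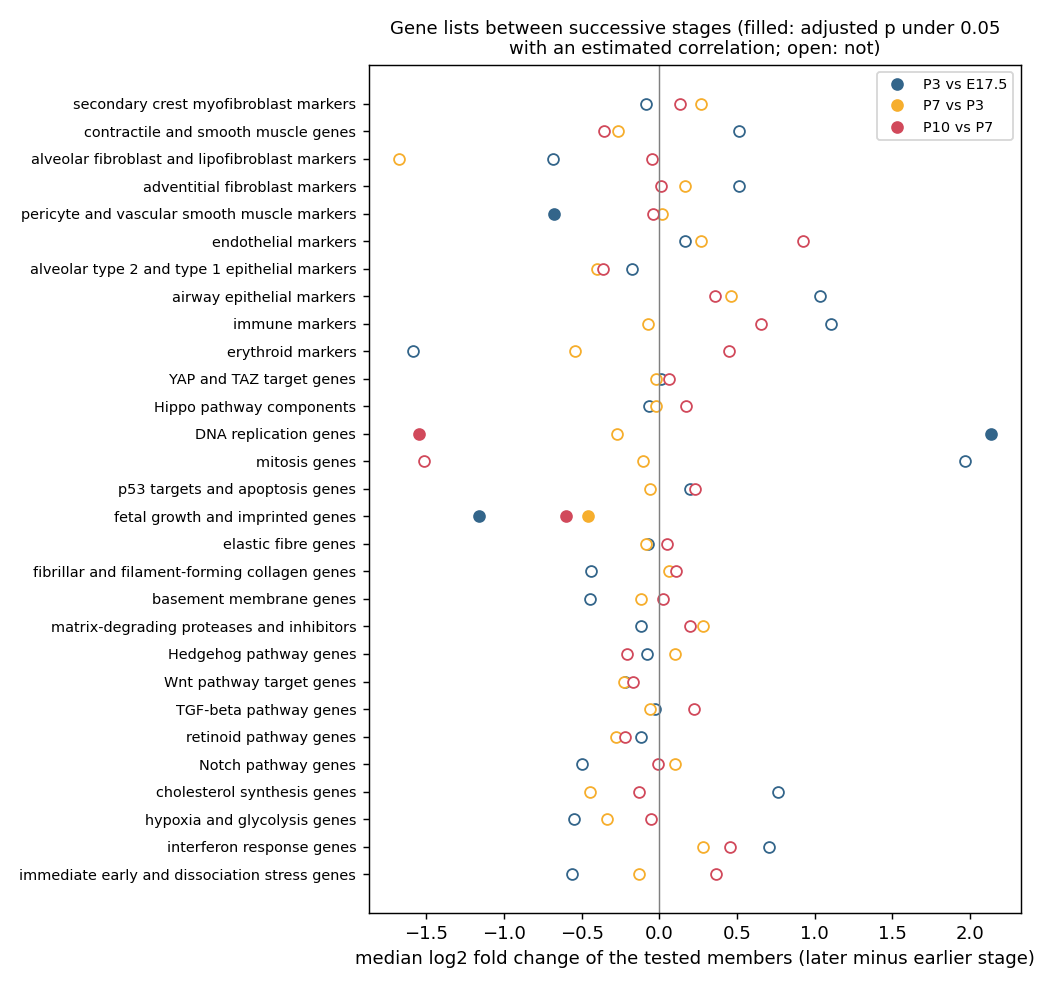
Median log2 fold change of the tested members of each gene list (horizontal axis, later minus earlier stage) for the 29 lists (vertical axis) and the 3 pairs of successive stages (colours); filled points had adjusted p under 0.05 with an estimated correlation and open points did not. The DNA replication list lay at 2.13 in P3 vs E17.5 and at -1.55 in P10 vs P7, and the fetal growth list at -1.16, -0.46 and -0.60 in the order of the stages.

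Between P3 and P7, fetal growth genes went on falling. Igf2, insulin-like growth factor II (chromosome 7, 142650766 to 142666816, minus strand), was the 1 gene of 16827 that passed. It went from 36.1 ± 4.20 to 5.84 ± 0.78 CPM (log2 fold change -2.63, SE 0.27, adjusted p = 0.0233, n = 3 per stage). Without 1 of the 6 libraries compared its log2 fold change lay between -2.73 and -2.54, but the call ended. Adjusted p was 0.0712, 0.0590 and 0.138 without P3 replicates 1, 2 and 3, and 0.0888, 0.222 and 0.104 without P7 replicates 1, 2 and 3. The fetal growth list passed (median -0.46, adjusted p = 4.55e-17, and adjusted p = 0.00790 with an estimated correlation), with 1 of 16 members lower over all genes and 9 lower adjusted over the list alone. Mki67 stood at 85.6 and 89.1 CPM (0.06, SE 0.21) and the DNA replication gene Pcna at 105 ± 13.7 and 86.9 ± 7.12 (-0.28, SE 0.12, adjusted p = 0.325). The DNA replication list was lower, with 19 of 22 estimates negative and 0 passing, also adjusted over the list alone (median -0.27, adjusted p = 0.00230, and adjusted p = 0.585 with an estimated correlation). Eln stood at 533 and 1569 ± 344 CPM (1.56, SE 0.24, adjusted p = 0.0643). Aldh1a1, a retinoic acid synthesis enzyme, stood at 27.2 ± 6.10 and 10.3 ± 1.03 (-1.40, SE 0.24, adjusted p = 0.0782).

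No member of the 19 alveolar fibroblast and lipofibroblast markers passed in P7 vs P3, and 8 were lower adjusted over the list alone, with a median log2 fold change of -1.68 (adjusted p = 1.57e-10, and adjusted p = 0.316 with an estimated correlation). Their summed level was 613 ± 115 CPM at P3 and 215 ± 54.7 at P7, and Limch1 stood at 175 ± 20.1 and 31.7 ± 16.7 CPM. Alveolar epithelial markers moved the same way, with 18 of 19 estimates negative, 0 passing and 1 lower adjusted over the list alone (median -0.40, adjusted p = 0.000786, and adjusted p = 0.585 with an estimated correlation). The 19 cholesterol synthesis genes all had negative estimates (median -0.45, adjusted p = 1.61e-07, and adjusted p = 0.338 with an estimated correlation), with 0 passing, also adjusted over the list alone. Among them Hmgcs1 stood at 44.1 and 26.7 CPM. Secondary crest myofibroblast markers were the 1 list that passed upwards, with 13 of 18 estimates positive (median 0.27, adjusted p = 0.0298, and adjusted p = 0.585 with an estimated correlation). That call ended without P3 replicates 2 and 3 and P7 replicate 3 (adjusted p = 0.0698, 0.0585 and 0.0710). Contractile and smooth muscle genes were lower, with 15 of 20 estimates negative (median -0.27, adjusted p = 0.0195, and adjusted p = 0.608 with an estimated correlation), and had adjusted p = 0.164 without P7 replicate 2. No member of either list passed, also adjusted over the list alone. Hypoxia and glycolysis genes were lower too (median -0.33, adjusted p = 0.000487, and adjusted p = 0.258 with an estimated correlation), as were Wnt pathway targets (median -0.23, adjusted p = 0.0334, and adjusted p = 0.498 with an estimated correlation). In these 2 lists 0 members passed, and 1 and 2 were lower adjusted over the list alone. The Wnt call ended without E17.5 replicate 3, P3 replicate 1 and P7 replicate 2 (adjusted p = 0.0575, 0.0769 and 0.0536). Yap1 (55.7 and 48.2 CPM, adjusted p = 0.398), Wwtr1 (59.4 and 47.5, adjusted p = 0.491) and Ctgf (272 and 184, adjusted p = 0.577) did not pass, nor did Cyr61 (513 and 553, adjusted p = 0.926). The YAP and TAZ target list did not pass either (adjusted p = 0.781), with its test above 0 and its median of -0.018 and mean of -0.033 below 0. At an unadjusted p under 0.05 there were 2399 genes, where chance gives 841, and DESeq2 called 476. Without E17.5 replicate 1, which is in the fit but not in the comparison, 77 genes passed, and 0 passed without P3 replicate 1 or 3 or P7 replicate 1 or 2. The count was 2 without E17.5 replicate 2 or P10 replicate 2, and 3 without E17.5 replicate 3 or P10 replicate 1. With the preset correlation 9 lists passed, 1 up and 8 down, of which 1 held with an estimated correlation, and other splits of the 6 libraries gave up to 10.

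Between P7 and P10, proliferation genes fell, and Eln, Mgp and Col3a1 rose. Of 22 DNA replication genes 20 fell, and 22 adjusted over the list alone (median log2 fold change -1.55, adjusted p = 2.60e-47, and adjusted p = 0.0225 with an estimated correlation). Mcm6 went from 31.1 ± 2.32 to 10.6 ± 2.61 CPM (-1.55, SE 0.18, adjusted p = 0.00513), Mcm5 from 18.1 to 4.36 and Gmnn, which encodes geminin, from 12.4 to 3.02. Of 20 mitosis genes 16 fell, and 20 adjusted over the list alone (adjusted p = 2.74e-33, and adjusted p = 0.126 with an estimated correlation). Mki67 stood at 89.1 ± 2.16 and 35.5 ± 10.5 CPM. Eln rose from 1569 ± 344 to 4633 ± 390 CPM (1.56, SE 0.24, adjusted p = 0.0132). Mgp, matrix Gla protein (chromosome 6, 136872435 to 136875823, minus strand), rose from 95.3 ± 40.1 to 684 ± 78.7 (2.84, SE 0.33, adjusted p = 0.00513) and Col3a1 from 2682 ± 169 to 3930 ± 216 (0.55, SE 0.13, adjusted p = 0.0428). Of 19 elastic fibre genes 1 rose (2 rose and 1 fell adjusted over the list alone, list adjusted p = 0.564), of 15 fibrillar collagen genes 2 (2 over the list alone, 0.204) and of 17 basement membrane genes 2 (3 over the list alone, 0.564). The call of Eln ended without P7 replicate 1 (adjusted p = 0.0540), P7 replicate 3 (0.0643), P10 replicate 2 (0.0607) or P10 replicate 3 (0.0680).

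Of 16 fetal growth and imprinted genes 6 fell in P10 vs P7, and 9 adjusted over the list alone (median -0.60, adjusted p = 1.61e-07, and adjusted p = 0.0393 with an estimated correlation). H19 stood at 53.4 ± 19.2 and 9.49 ± 3.98 CPM and Meg3 at 58.2 and 31.9. Of 18 TGF-beta pathway genes 2 rose, and 4 adjusted over the list alone (adjusted p = 0.0195, and adjusted p = 0.251 with an estimated correlation). They were Pmepa1 (log2 fold change 0.71, SE 0.15) and Bhlhe40 (26.5 to 54.5 CPM). Of 15 matrix-degrading proteases and inhibitors 2 rose, and 5 adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.185 with an estimated correlation), namely Adamts1 (169 to 421 CPM) and Adamts2 (79.7 to 124). Other genes with high fold changes were Fmo2 (29.4 to 154 CPM), the metallothionein Mt1 (3.70 to 18.6), Hr (7.38 to 35.7), the mitochondrial carrier Ucp2 (13.5 to 64.1) and Slc25a33 (5.30 to 22.1). Slfn9 (13.5 to 2.90 CPM) and Thsd4 (22.3 to 5.12) were among the lowest. So was the processed pseudogene Pcna-ps2 (log2 fold change -1.89, SE 0.43), whose values are uncertain because of a near-identical parent gene. Yap1 (48.2 and 58.1 CPM, adjusted p = 0.183), Wwtr1 (47.5 and 61.6, adjusted p = 0.323), Ctgf (184 and 249, adjusted p = 0.611) and Cyr61 (553 and 563, adjusted p = 0.978) did not pass. Of 21 YAP and TAZ target genes 1 rose, also adjusted over the list alone, and the list did not pass (adjusted p = 0.336). It was F3 (4.60 to 11.3 CPM, adjusted p = 0.0377), whose call ended without P3 replicate 2, P7 replicates 1, 2 and 3, and P10 replicates 2 and 3 (adjusted p = 0.0511, 0.103, 0.114, 0.140, 0.113 and 0.126). The 29 Hippo pathway components did not pass as a list (adjusted p = 0.0530), and 0 passed singly, also adjusted over the list alone. Of 10 interferon response genes 1 rose, and 3 adjusted over the list alone (adjusted p = 0.0298, and adjusted p = 0.251 with an estimated correlation). The Hedgehog pathway list was lower, with 0 of 12 passing and 1 lower adjusted over the list alone (adjusted p = 0.0392, and adjusted p = 0.280 with an estimated correlation). The interferon call ended without P7 replicate 2 and P10 replicates 1 and 3 (adjusted p = 0.0587, 0.149 and 0.0585), and the Hedgehog call without P7 replicates 2 and 3 and P10 replicate 1 (0.0692, 0.0629 and 0.247).

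No contractile and smooth muscle gene passed in P10 vs P7, also adjusted over the list alone, with 18 of 20 estimates negative (median -0.36, adjusted p = 0.00216, and adjusted p = 0.575 with an estimated correlation). Their summed level was 7331, 4908 and 5128 CPM in P10 replicates 1, 2 and 3, against 7635 ± 855 at P7. The endothelial markers moved beside them, with 0 of 15 passing, also adjusted over the list alone, and a median of 0.92 (adjusted p = 0.00446, and adjusted p = 0.607 with an estimated correlation). Their sums were 63.9, 193 and 181 CPM in the same P10 libraries. The immune list was also higher, with 0 of 12 passing, also adjusted over the list alone (median 0.66, adjusted p = 0.0279, and adjusted p = 0.483 with an estimated correlation). It had adjusted p = 0.180 and 0.0667 without P7 replicate 1 and P10 replicate 2. The endothelial list lost its call without P7 replicate 1 (adjusted p = 0.0503), P10 replicate 2 (0.105) or P10 replicate 3 (0.0855).

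**Figure D3:**
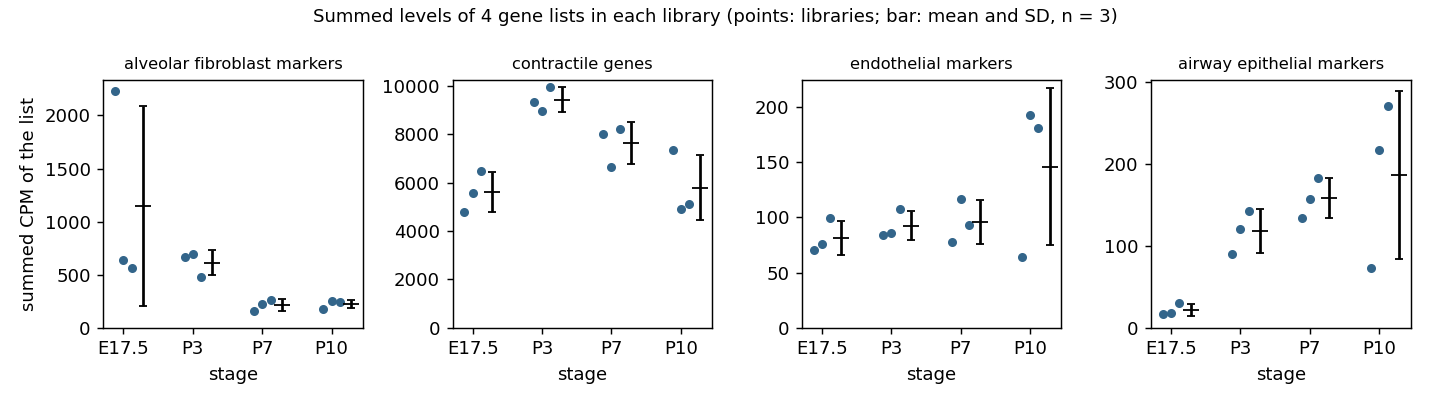
Summed CPM (vertical axes) of 4 gene lists in each library at each stage (horizontal axes); points are the 3 libraries and the bar gives their mean and SD. E17.5 replicate 1 had 2232 CPM of alveolar fibroblast markers against 637 and 564 in the other E17.5 libraries, and P10 replicate 1 had 63.9 CPM of endothelial markers against 193 and 181.

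In all, 613 genes passed in P10 vs P7, 235 higher and 378 lower at P10, of which 91 and 216 differed at least 2-fold, and 3406 had an unadjusted p under 0.05. This count was unstable: it fell steeply when any 1 of several libraries was left out, and was 794 without P10 replicate 1. It was 55, 100 and 46 without P7 replicates 1, 2 and 3, 23 and 25 without P10 replicates 2 and 3, and 359 and 283 without P3 replicates 1 and 2. Of 48 calls of named genes in this comparison, 39, 30 and 39 ended without P7 replicates 1, 2 and 3, and 7, 41 and 42 without P10 replicates 1, 2 and 3. Of these calls, 10, 16 and 4 ended without P3 replicates 1, 2 and 3, and 2 and 1 without E17.5 replicates 2 and 3. With the preset correlation 11 lists passed, of which 2 held with an estimated correlation, and other splits of the 6 libraries gave up to 11.

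Genes that passed both across birth and again after P7 mostly turned back. Of the genes that passed in both P3 vs E17.5 and P10 vs P7, 2 comparisons that share no library, 286 rose and then fell where independent lists would share 49.4 (Fisher's exact test across genes, p = 7.34e-176). Another 130 fell and then rose where independent lists would share 28.3 (Fisher's exact test, p = 1.68e-58). Both p treat genes as independent, which co-regulated groups such as the DNA replication and mitosis genes are not, so they can be far too low and only describe the overlap. Both comparisons also come from 1 model with 1 estimate of the spread per gene. Genes of low spread can therefore pass in both, so the numbers for independent lists are no exact expectation. In both comparisons 17 rose and 15 fell, where independent lists would share 30.7 and 45.5. Of the 22 DNA replication genes 20 rose and then fell, and of the 20 mitosis genes 15. Chaf1b, a chromatin assembly factor, stood at 1.19, 12.3, 9.98 and 2.46 CPM in the order of the stages, the maintenance methyltransferase Dnmt1 at 15.9, 40.3, 35.6 and 17.2. Among those that fell and then rose, Mgp stood at 1690, 146, 95.3 and 684 CPM, Klf9, a hormone-responsive transcription factor, at 75.7, 31.2, 34.8 and 86.0, and Dmpk at 67.0, 24.4, 28.1 and 48.1. Among the immediate early and dissociation stress genes, which also respond to handling, 1 of 17 fell and then rose. Of the 17 members 3 fell in P3 vs E17.5, also adjusted over the list alone (median -0.57, adjusted p = 0.0282, and adjusted p = 0.641 with an estimated correlation), among them Socs3 (320 to 136 CPM). In P10 vs P7 1 rose, and 2 adjusted over the list alone (median 0.36, adjusted p = 0.0139, and adjusted p = 0.608 with an estimated correlation). That list had adjusted p = 0.0511 and 0.0830 without E17.5 replicate 1 and P3 replicate 3 in the first comparison, and 0.204 and 0.0772 without P7 replicate 2 and P10 replicate 3 in the second. The 416 reversals became 237 and 185 without P3 replicates 1 and 2, 40, 72 and 32 without P7 replicates 1, 2 and 3, and 17 and 16 without P10 replicates 2 and 3.

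Between the first and last stage, P10 vs E17.5, fetal growth genes and pericyte markers were lower as lists. Of 16 fetal growth and imprinted genes 14 fell and none rose, 14 and 1 adjusted over the list alone (median log2 fold change -2.32, adjusted p = 3.52e-37, and adjusted p = 0.000356 with an estimated correlation). Igf2 went from 197 to 2.38 CPM (-6.35, SE 0.32, adjusted p = 1.61e-06). H19 went from 4386 to 9.49 (-8.85, SE 0.45) and the RNA-binding protein gene Igf2bp3 from 16.2 to 0.65 (-4.62, SE 0.30). Of 16 pericyte and vascular smooth muscle markers 7 fell and 1 rose, 8 and 1 adjusted over the list alone (adjusted p = 0.000377, and adjusted p = 0.0492 with an estimated correlation). Pdgfrb was the 1 that rose, from 31.7 to 84.4 CPM. Rgs5, which had fallen across birth, stood at 60.1, 87.1 and 70.3 CPM in E17.5 replicates 1, 2 and 3. It stood at 47.4, 72.6 and 84.4 CPM in P10 replicates 1, 2 and 3. In P10 vs P7 1 of the 16 markers rose, and 3 adjusted over the list alone (list adjusted p = 0.536 by camera with the preset correlation). Of 18 hypoxia and glycolysis genes 13 fell, also adjusted over the list alone (adjusted p = 8.44e-09, and adjusted p = 0.0789 with an estimated correlation). Of 13 Wnt pathway target genes 9 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.000482, and adjusted p = 0.258 with an estimated correlation). Notum went from 65.5 to 5.41 CPM and Axin2 from 94.3 to 53.4.

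Of 19 elastic fibre genes 5 rose and 9 fell in P10 vs E17.5, with the same counts adjusted over the list alone (adjusted p = 0.137). Lox went from 352 to 29.6 CPM and Loxl1 from 34.6 to 160, while Eln stood at 4001 and 4633 CPM (0.21, SE 0.24, adjusted p = 0.591). Of 17 basement membrane genes 10 fell and 1 rose, 11 and 2 adjusted over the list alone (adjusted p = 0.00483, and adjusted p = 0.258 with an estimated correlation), and Nid2, which encodes a nidogen, went from 32.9 to 11.5 CPM. Tgfb3 went from 30.8 to 147 CPM (2.25, SE 0.16), Tgfb2 from 16.2 to 104 and Aspn from 8.71 to 414 (5.56, SE 0.39). Of 29 Hippo pathway components 4 rose and 2 fell, 4 and 3 adjusted over the list alone (adjusted p = 0.484), with Amotl1 at 32.6 and 86.4 CPM (1.41, SE 0.09). Of 21 YAP and TAZ target genes 6 rose and 1 fell, 6 and 2 adjusted over the list alone (adjusted p = 0.0334, and adjusted p = 0.227 with an estimated correlation). Without E17.5 replicate 3 that list had adjusted p = 0.0509. Ctgf rose from 67.2 to 249 CPM (1.89, SE 0.44, adjusted p = 0.0149), a call that ended without E17.5 replicate 1 (1.64, adjusted p = 0.0508). Of 19 alveolar fibroblast and lipofibroblast markers 11 fell and 1 rose, 15 and 1 adjusted over the list alone (adjusted p = 5.68e-06, and adjusted p = 0.507 with an estimated correlation). Their summed level was 2232, 637 and 564 CPM in E17.5 replicates 1, 2 and 3, so replicate 1 stood apart, and 225 ± 40.0 at P10. Of 15 adventitial fibroblast markers 4 rose and 1 fell, 5 and 2 adjusted over the list alone (adjusted p = 0.000482, and adjusted p = 0.429 with an estimated correlation).

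The highest fold changes in P10 vs E17.5 included the matrix protein gene Tnxb (0.16 to 44.2 CPM), the extracellular superoxide dismutase Sod3 (0.99 to 53.6) and Adam33 (0.56 to 30.7). The lowest included Hif3a (53.9 to 0.13 CPM), Col6a4 (59.9 to 0.45) and Igf2bp1 (11.7 to 0.040). Terc, the telomerase RNA, stood at 11.6, 17.7 and 6.62 CPM in E17.5 replicates 1, 2 and 3. It stood at 2.80 ± 1.35 CPM at P3 and 1.35 ± 0.52 at P7 and was listed at 0 in the P10 libraries. Immune markers moved beside these groups, with 5 of 12 higher, also adjusted over the list alone, among them Cd74 (0.30 to 5.95 CPM). That list had adjusted p = 0.000518, and adjusted p = 0.258 with an estimated correlation. Other cell-type markers moved too. Of 15 endothelial markers 2 rose (adjusted p = 0.0165, and adjusted p = 0.697 with an estimated correlation) and of 6 airway markers 2 (adjusted p = 0.00939, and adjusted p = 0.512 with an estimated correlation), also adjusted over each list alone. Of 19 alveolar epithelial markers 3 fell, and 6 adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.706 with an estimated correlation). Of 6 erythroid markers 4 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0473, and adjusted p = 0.535 with an estimated correlation). The endothelial call ended without P10 replicates 2 and 3 (adjusted p = 0.105 and 0.0837) and the alveolar epithelial call without E17.5 replicate 3 and P10 replicate 1 (0.09996 and 0.430). The erythroid call ended without E17.5 replicates 1 and 2, P3 replicate 3 and P10 replicates 1 and 3 (0.0717, 0.126, 0.0632, 0.130 and 0.0536). In all, 3077 genes passed in P10 vs E17.5, 1479 higher and 1598 lower at P10, of which 851 and 809 differed at least 2-fold. With upper-quartile scaling the balance turned, with 1791 higher and 1298 lower. With the preset correlation 14 lists passed, of which 2 held with an estimated correlation, and other splits of the 6 libraries gave up to 12.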

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

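The length-rescaled, protein-coding, 7SL and 7SK, limma-trend settings and the fit without both doubted libraries were chosen after seeing the data. Causes were not tested unless stated. In the main test of P7 vs P3 1 gene passed, and 2399 had an unadjusted p under 0.05. Genes passing numbered 4 with upper-quartile scaling, 3 without a filter, 18 with at least 5 CPM in 3 libraries, 476 with DESeq2 and 18 with limma-voom. They numbered 9 in the fit on the 6 libraries compared, 0 for a fold over 1.5, 14 with length-rescaled values and 37 with protein-coding genes. Limma-trend gave 25, 21 and 27 at pseudocounts of 1, 0.1 and 5, and the fit without E17.5 replicate 1 and P10 replicate 1 gave 271. P10 vs P7 (613) gave 307 without a filter, 1346 with DESeq2, 383 on the 6 libraries, 10 for a fold over 1.5 and 1124 without both libraries; reversals (416) were 217, 753 and 667 without a filter, with DESeq2 and without both libraries. P3 vs E17.5 (4225) gave 2587 on the 6 libraries and 1255 for a fold over 1.5, and P10 vs E17.5 (3077) gave 1577 and 1178. The stricter hypothesis of a fold over 1.5 lowers counts by construction, while the cause of the lower counts on the 6 libraries was not tested.

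Leaving out 1 library gave 0 to 77 genes in P7 vs P3, 23 to 797 in P10 vs P7, 16 to 525 reversals, 3040 to 4360 genes in P3 vs E17.5, 2056 to 3129 in P10 vs E17.5 and 4153 to 5520 over the stages. Lists passing were 3, 1, 2 and 2 with an estimated correlation (13, 9, 11 and 14 with the preset one), 3 with fry in P7 vs P3, and 8 in P10 vs E17.5 with at least 5 CPM. None of the list results that had passed changed direction in the settings with list tests (47 results, and 40 with at least 5 CPM). In P10 vs E17.5 upper-quartile scaling turned the balance of genes from 1479 higher and 1598 lower to 1791 and 1298. Upper-quartile scaling moved the median of all genes by at most 0.08 on the log2 scale.

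The replicate numbers did not pair the libraries: residuals of same-numbered libraries correlated between -0.19 and 0.14 over 18 pairs, and others between -0.20 and 0.22. With the replicate block 0 genes passed in P7 vs P3 and 310 in P10 vs P7, with 227 reversals, and Cyr61 P7 vs P3 was -0.013.

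Estimates that changed sign belonged to genes that had not passed. Cyr61 P7 vs P3 was -0.076 with limma-voom and -0.073, -0.073 and -0.071 with limma-trend, and lay between -0.58 (without P7 replicate 1) and 0.37 with 1 library left out. Cyr61 P10 vs P7 was -0.24, -0.19 and -0.010 without P7 replicate 2, P7 replicate 3 and P10 replicate 3, up to 0.72. Cyr61 P10 vs E17.5 was 0.014 without E17.5 replicate 1, down to -0.29, and 0.032 without both libraries. Acta2 P10 vs E17.5 was 0.051 with upper-quartile scaling, 0.0024 with at least 5 CPM, and 0.32, 0.16 and 0.081 without E17.5 replicate 3, P10 replicate 2 and P10 replicate 3, down to -0.33. Yap1 P10 vs E17.5 was 0.061 and 0.0032 with those settings, and 0.016, 0.032 and 0.030 without E17.5 replicate 2, P10 replicate 2 and P10 replicate 3, down to -0.12. Wwtr1 P3 vs E17.5 lay between -0.021 (without P3 replicate 3) and 0.25, Wwtr1 P10 vs E17.5 between -0.043 (without P10 replicate 1) and 0.30, and Pdgfra P7 vs P3 between -0.024 (without P7 replicate 2) and 0.21.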

Other observations

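The tests of cell mixture, length scaling and spread here were chosen after their results were seen, and the glucocorticoid test was fixed before its targets were looked at. In P3 vs E17.5, 10 of 19 cholesterol synthesis genes rose and none fell, 15 and 1 adjusted over the list alone (adjusted p = 3.19e-05, and adjusted p = 0.483 with an estimated correlation). Hsd17b7 stood at 5.65 and 15.5 CPM and Sqle at 6.44 and 15.7. Of 11 retinoid pathway genes 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.440), with Aldh1a1 at 63.9 and 27.2 CPM. Of 10 interferon response genes 4 rose in P10 vs E17.5, also adjusted over the list alone (adjusted p = 0.00413, and adjusted p = 0.149 with an estimated correlation). Gbp2 went from 1.41 to 5.41 CPM and Irf1 from 154 to 345.

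The lower alveolar fibroblast markers at P7 than at P3 may come from the makeup of the sort. A lower share of endothelial, alveolar epithelial, airway and immune cells all together is argued against, since it would have moved all 4 of their lists down. Of these lists the highest median log2 fold change was 0.46, for 6 airway genes (95% bootstrap interval -0.00075 to 1.98, and 0.21 to 1.21 with 1 library left out). The bootstrap intervals of these lists are over genes, not libraries. The endothelial median was 0.27 (0.02 to 0.43, and -0.053 to 0.57 with 1 library left out). The alveolar epithelial one was -0.40 (-0.57 to -0.27) and the immune one -0.071 (-0.61 to 0.30), so fewer alveolar epithelial cells stay open. The erythroid list was not part of this test. Its median was -0.54, with 5 of 6 estimates negative (adjusted p = 0.171 by camera with the preset correlation), so fewer erythroid cells stay open too. That 94.7% of the alveolar fibroblast markers lay below 0 restates the pattern and is no evidence, so fewer alveolar fibroblasts and lower expression in the same cells cannot be told apart without single cells. A change with age was not tested.

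Contractile genes were lower and endothelial markers higher in P10 replicates 2 and 3. Dilution of sorted cells whose expression did not change is argued against, since without P10 replicate 1 the contractile median was -0.60 and that of the secondary crest myofibroblast markers 0.22 (95% bootstrap interval over genes, not libraries, -0.12 to 0.49, 12 above and 6 below 0). Markers that rise in the sorted cells could hide dilution. Aspn stood at 384, 391 and 466 CPM in P10 replicates 1, 2 and 3, against 204, 251 and 294 at P7. Tgfbi went the other way, at 1774, 1257 and 999 against 1941, 1740 and 1937. The sums of the secondary crest list, 4816, 4278 and 4096 CPM in P10 replicates 1, 2 and 3 against 4573 ± 201 at P7, also leave dilution open as part of the cause. All endothelial markers (100%) lay above 0, which restates the pattern, so carried-over endothelial cells and expression in the sorted cells cannot be told apart. Ramp2, the most abundant of them, stood at 31.8, 54.3 and 49.8 CPM in P10 replicates 1, 2 and 3 and 44.2 ± 4.11 at P7. A change with age was not tested.

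Only 1 gene passed in P7 vs P3. With length-rescaled values 14 genes passed, but that fit also left out genes without a transcript length. Other gene sets without rescaling gave 37 with protein-coding genes and 18 with at least 5 CPM in 3 libraries. The 14 genes therefore cannot be tied to the length scaling, which stays open as part of the cause. Spread added by E17.5 replicate 1 could account for part of the low count, since 77 genes passed without that library. But the fit on the 6 libraries compared, which holds no E17.5 library, called 9, so what limits the count cannot be told apart.

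A hypothesis was that glucocorticoid signalling was high at E17.5 and rose again by P10. In P3 vs E17.5 the 18 listed glucocorticoid targets had a median log2 fold change of -1.09, with 8 lower and 2 higher past the threshold, and p = 0.0335 by camera with an estimated correlation. In P10 vs P7 the median was 0.57, with 16 of 18 estimates above 0, 0 rising and 1, Fkbp5, falling past the threshold, and p = 0.0482 by camera with an estimated correlation. Both missed the threshold of 0.025 set beforehand, so the hypothesis is unresolved.

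Other splits of the libraries into groups of the same sizes were refitted. For the 4 stages, 1 of 100 splits, the real one, gave 5401 genes or more and the highest other gave 3675; for reversals it was again 1 of 100, with 416 against 25. Chance can be excluded only for the grouping of these 12 libraries as a whole, and not between animals, which the labels do not tell apart. These splits mix stages, so the change across birth could by itself set the real counts apart, and they do not test P10 vs P7, on which each reversal also rests. Without P10 replicates 2 and 3 there were 17 and 16 reversals. These smaller fits cannot be set against the 25 of a split of all 12 libraries, and splits of them were not run. Each pair of stages has 10 splits, too few for a share under 0.05. All but the real split hold both stages in each group in unequal numbers, so they keep part of the stage difference. The rest of that difference goes into the spread within groups, which lowers calls of single genes by construction. The low gene counts of the other splits are therefore no chance level and no support for the real counts. For genes, the real counts and the highest others were 4225 and 0, 1 and 1, 613 and 2, and 3077 and 2, with 1, 2, 1 and 1 splits as large, in the order P3 vs E17.5, P7 vs P3, P10 vs P7 and P10 vs E17.5. For lists with the preset correlation they were 13 and 11, 9 and 10, 11 and 11, and 14 and 12, with 1, 3, 4 and 1 splits as large.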
